A study of Mus musculus with 16 samples.

How the data were processed

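Total RNA from mouse embryonic fibroblasts was measured on 16 Illumina bead arrays, with 2 genotypes, wild-type (Wt) and Hmgb1 knockout (KO), in 3 culture states called phases here: cycling, G1-synchronised and S-synchronised. Each genotype had 3 arrays in cycling cells, 3 in G1 and 2 in S, which makes 6 groups. Per the labels, RNA was extracted with mirVana, checked on a Bioanalyser, and labelled as biotinylated cRNA. The arrays lay on 2 slides of 8 arrays. Slide 1 held the cycling arrays and the G1 pair numbered 3, and slide 2 held the G1 pairs numbered 1 and 2 and the S arrays.

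The authors processed the arrays with BeadStudio 3.0 according to their processing notes. The deposited non-normalized file gives the average probe intensity of each array and, per the file headers, a detection p-value for each probe and array. The authors' value table holds intensities on a linear scale with a median of 118 on every array and nearly the same distribution throughout, as quantile normalization leaves it. The method is not stated. The order of the probes on each array was the same in both files (rank correlation 1 on every array). The non-normalized intensities were used for every main result, and the authors' table served as an alternative.

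The file holds 25697 probes. The probe table provided with the series matrix gave 1 symbol for 23978 of them, which cover 16593 genes, and none for 1719. Probes without a symbol are given by their Illumina identifier. No genome build is stated for the probes, so no coordinates are given. Mean intensity per array ranged from 394 to 776, and 9970 to 12354 probes per array (38.8% to 48.1%) had a detection p under 0.01. The number of arrays limits the precision of every value.

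Intensities were background-corrected by the normexp model with the background taken from the detection p-values, an offset of 16 was added, and the arrays were quantile normalized on the log2 scale (neqc in limma 3.58.1 under R 4.3.3, with statmod 1.5.0). Probes with a detection p under 0.01 on every array of at least 1 of the 6 groups were tested, 12078 probes of 8428 genes, with 687 probes lacking a symbol. The limma model had a mean for each of the 6 groups and was fitted to all 16 arrays, so that the S groups of 2 arrays shared the estimate of the spread with the others. Tests were two-sided, moderated by eBayes, and adjusted by the Benjamini-Hochberg method over the 12078 probes. A call means an adjusted p under 0.05. The genotype difference was tested within each phase and as the mean of the 3 phases. For that mean, the replicate number within genotype, planned as the fibroblast line, was a random block (consensus correlation -0.0106). The difference of the genotype effects was tested for G1 against cycling and for S against G1. The phases were compared, as the mean over genotypes, for G1 against cycling and S against G1. Values are log2 differences with the standard error (SE) from limma. Where a probe was detected on no array of the lower group, the fold is a lower limit against the lowest value of a detected probe on each of those arrays, or against the probe's own value where that was higher, written as "at least". The same limit, added after the data were seen, is given where the probe was detected on at most 50% of the lower group's arrays, and folds of probes detected on more but not all of them include values at background.

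The series description derives each Wt and KO pair from embryos of a mother heterozygous for Hmgb1, with 3 mothers, and the labels number the samples of each group. Deviations from the group mean on arrays of the same number correlated at 0.196, 0.189 and 0.388 in cycling cells, 0.423, 0.403 and 0.357 in G1 and 0.0644 in S. In cycling cells, Wt 1 with KO 2 and Wt 2 with KO 1 gave 0.246 and 0.226, above the values of numbers 1 and 2 themselves, so numbers 1 and 2 could not be told apart there. In G1, Wt 2 with KO 3 and Wt 3 with KO 2 gave 0.276 and 0.248, below the values of the same number. The numbers were taken as pairs within a phase from the description. The fit without a pair block was the main one and fits with a block were alternatives. The planned block was the replicate number. Values with the pair block below come from a block for each of the 8 pairs within its phase, added after the data were seen.

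Lists of genes were tested with camera on the moderated statistics with a preset correlation of 0.01, 1 probe per gene (the brightest on average over the 16 arrays), and adjustment over the lists. Of 40 lists, 37 had at least 5 tested genes. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were alternatives. Counts of list members past the threshold are over all probes tested, and counts adjusted over the list alone are given beside them.

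The groups, tests, gene lists, alternatives and the rule for the genes named were chosen before the data were examined, except where tests or alternatives are said to have been chosen later. The rule takes, for the genotype difference, up to 12 probes with the largest rise and 12 with the largest fall among those past the threshold and changed the same way in every pair. For a phase difference it takes 8 on each side, changed the same way for every replicate number of each genotype measured in both phases, and for a difference between genotype effects the 5 of smallest p on each side. Up to 4 members of smallest p are named from each list.

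The alternatives were no background correction, median scaling in place of quantile normalization, the authors' table, no filter on dim probes, probes detected on all 16 arrays alone, the slide, pair or replicate number within genotype as a block, eBayes with trend and robust options, the arrays of the compared groups alone, and leaving out arrays in turn. Alternatives added later left out 2 arrays or 2 pairs that stood apart, treated detection of the Y-linked gene Eif2s3y as a block, or kept to the arrays of 1 slide. The scripts were tested on simulated data of the same layout, with 100 probes changed by 1 and 100 by 2 log2 units among 12078. At 1 log2 unit, 34% of the changed probes were called in the cycling comparison, 43% in G1, 14% in S and 83% in the mean over phases, and at 2 log2 units 90%, 92%, 66% and 100%. Of the probes called, 5.34%, 3.57%, 2.44% and 5.67% were unchanged ones, and 9.33% for the KO effect in G1 against cycling. The simulated noise was independent between arrays, without pairs, slide effects or arrays that stand apart. These shares therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.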

Results

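Gene expression was measured in fibroblasts that carry or lack Hmgb1, which encodes an abundant chromatin protein that bends DNA and acts as an inflammatory signal outside the cell. The 16 arrays comprised 3 Wt and 3 KO arrays of cycling cells, 3 and 3 of G1-synchronised cells and 2 and 2 of S-synchronised cells. Mean intensity per array ran from 394 on KO_G1 replicate 1 to 776 on KO_cycling replicate 2. Arrays KO_G1 replicate 1 and Wt_cycling replicate 3 stood apart from the rest. The lowest correlation with an array of the same group was 0.881 for the former and 0.941 for the latter, and their mean for the oxidative phosphorylation list was -1.46 and -1.15 log2 units from the average of all arrays, against -0.29 to 0.35 on the other 14. The Y-linked gene Eif2s3y was detected on 10 arrays and the X-linked gene Xist on the other 6, and each Wt and KO pair matched in this respect.

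The knocked-out gene was read by 1 probe, which could not check the genotype labels. The Hmgb1 probe was detected on 1 of the 16 arrays, Wt_G1 replicate 2, with a detection p-value of 0.00251. Its values lay between 4.48 and 5.75 on the log2 scale, around the lowest values of detected probes on the arrays (5.16 to 5.97), so no fold is given. None of the tested genes of other HMG proteins passed limma between KO and Wt averaged over phases, with Hmgn2 at -0.48 (adjusted p = 0.221, limma) and Hmgb2 at -0.64 (adjusted p = 0.422, limma). Of 14 genes that lie near Hmgb1 none passed, with Katnal1 at -0.29 (adjusted p = 0.397, limma).

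The first question was which genes depend on Hmgb1 whatever the phase. Averaged over cycling, G1 and S cells, KO fibroblasts had less mRNA for the water channel Aqp1, the neutrophil chemokine Cxcl5 and the matrix metalloproteinase Mmp3. Aqp1 fell by 2.50 ± 0.20 log2 units (SE; 5.65-fold; 8 Wt and 8 KO arrays; probe ILMN_2980661), its probe ILMN_2756486 fell by 2.27 ± 0.20, and ILMN_2980663, detected on 4 of 8 KO arrays, was at least 4.57-fold lower. Cxcl5 (ILMN_1230278) fell by 2.48 ± 0.21, which is 5.56-fold, and Mmp3 (ILMN_2899041) fell by 1.86 ± 0.14, which is 3.63-fold, each in 8 of 8 pairs. Dlk1, an imprinted regulator of adipocyte differentiation, fell by 2.27 ± 0.31, the secreted Wnt modulator Sfrp2 by 2.06 ± 0.30 and the mesodermal homeobox gene Meox1 by 2.06 ± 0.33. The Mas-related receptor Mrgprf fell by 1.96 ± 0.18 and the surface antigen Ly6c1 by 1.93 ± 0.32. Adjusted p from limma was 3.25e-05 for Mmp3, 3.57e-05 for Cxcl5 and each Aqp1 probe, and at most 0.00497 for the others. The probes ILMN_1255416 and ILMN_2906728, which have no symbol, fell (-2.66 ± 0.30 and -2.64 ± 0.37). Aqp1, Cxcl5, Ltbp4 and Smpdl3b were the 4 named genes past the threshold in the same direction in each of the 3 phases tested singly, and Ltbp4 was named after its values were seen. With the pair block, the Aqp1 calls in G1 and in S and the Cxcl5 call in cycling cells ended.

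Other genes rose in KO cells. Uts2b, which encodes a urotensin peptide, was detected on no Wt array and was at least 2.70-fold higher in KO cells, in 8 of 8 pairs. In the G1 pair numbered 1, both values lay at background (4.40 in Wt and 4.52 in KO), so that pair does not show a rise. P2ry14, a receptor for UDP-glucose, and the Notch receptor gene Notch4 rose by 1.38 ± 0.14 each. The serotonin receptor gene Htr2b, detected on 4 of 8 Wt arrays, was at least 2.30-fold higher. The neuronal pentraxin gene Nptx2 rose by 1.73 ± 0.25 and Dner, which encodes a neuronal Notch ligand, by 1.52 ± 0.29. Ivl, which encodes the cornified envelope protein involucrin, was detected on 1 of 8 Wt arrays and was at least 1.95-fold higher. Ankrd1 and Parm1 rose by 1.48 ± 0.32 and 1.42 ± 0.31 at their strongest probes. Adjusted p from limma ran from 3.57e-05 for Uts2b to 0.0384 for the weaker Parm1 probe, and an unnamed probe, ILMN_2681913, rose by 1.43 ± 0.33 (adjusted p = 0.0402, limma). With the slide as a block, the calls of both Parm1 probes and of ILMN_2681913 ended (adjusted p of 0.0545, 0.0599 and 0.0527 in limma). In all, 249 probes, which cover 209 named genes and include 16 without a symbol, passed the threshold in limma, 110 higher and 139 lower in KO cells, and 195 of them moved the same way in all 8 pairs. With median scaling the count was 150 (50 higher, 100 lower), with the pair block 399, without the 2 arrays that stood apart 1184, without replicate number 1 in every group 39 and without number 2 it was 0 (336 at an unadjusted p under 0.05 in limma).

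**Figure D1:**
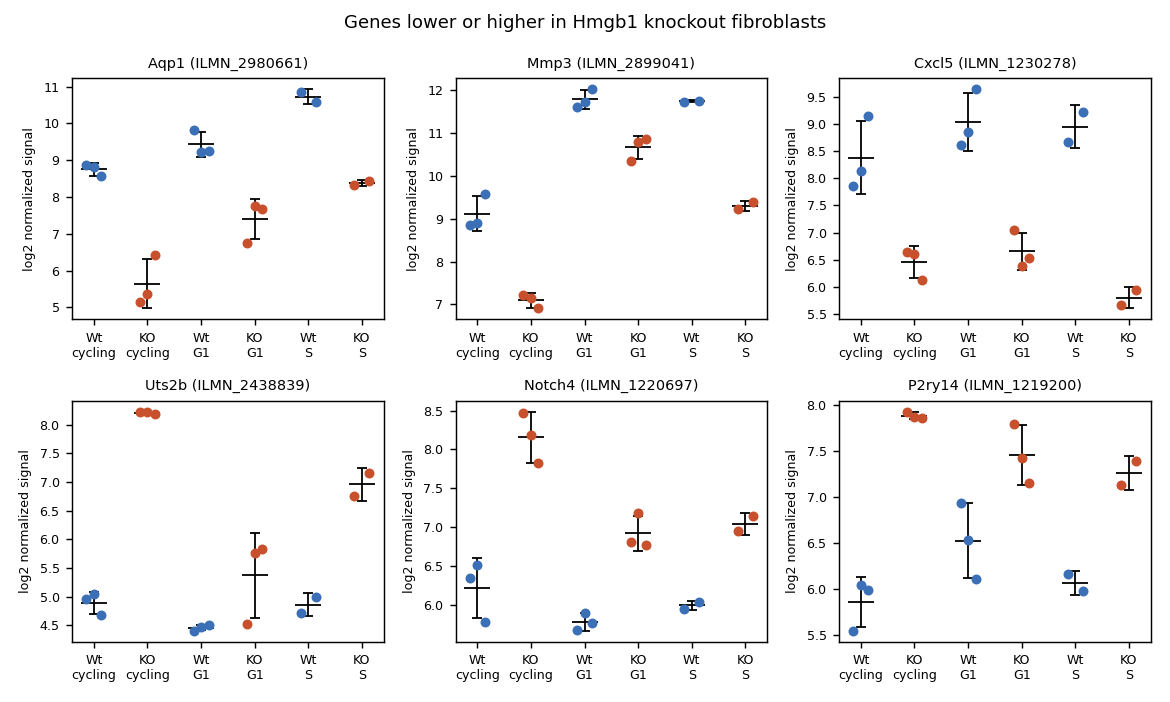
Normalized log2 signal of 6 genes on each array, grouped by genotype and phase; points are arrays, and bars are the group mean and standard deviation (3 arrays per group, 2 in S). The KO arrays lie below the Wt arrays of the same phase for Aqp1, Mmp3 and Cxcl5 and above them for Uts2b, Notch4 and P2ry14.

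The lists of cell-cycle genes had medians below 0 in KO cells, with few genes past the threshold singly. Of the 34 genes of the G2/M list, Nusap1 (-0.47 ± 0.10) and Ndc80 (-0.65 ± 0.15), which act on the mitotic spindle and kinetochore, fell past the threshold, and 7 fell when adjusted over the list alone. Of the 37 genes of the G1/S and replication list, the thymidine kinase gene Tk1 fell (-0.78 ± 0.18), and 4 fell when adjusted over the list alone. Dut, Pola2 and Uhrf1 had values of -0.61, -0.46 and -0.49 without passing. The list medians were -0.39 for G2/M and -0.27 for G1/S, and each list's mean was lower in KO cells in 8 of 8 pairs. Both lists had an adjusted p of 5.4e-10 in camera. With an estimated correlation, adjusted p = 0.344 for G2/M and 0.138 for G1/S, and in fry adjusted p was 0.0602 and 0.012.

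**Figure D2:**
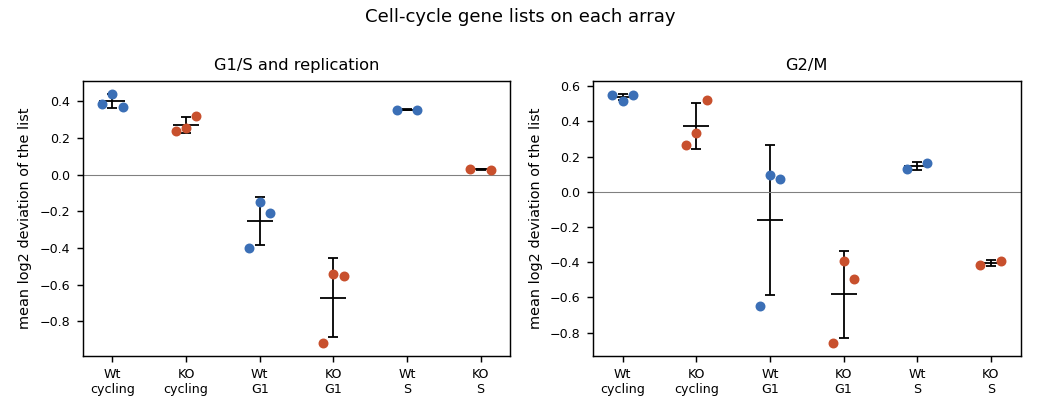
Mean log2 deviation of the G1/S and replication list and of the G2/M list from their average over the 16 arrays, per array; bars are the group mean and standard deviation. KO arrays had the lower group mean in every phase for both lists, and the G1 arrays lay below the cycling arrays.

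Imprinted genes were lower in KO cells, with a list median of -0.20 over 18 genes and a lower list mean in 8 of 8 pairs. Dlk1 fell, as did Dio3, which inactivates thyroid hormone (-0.92 ± 0.14). Mest and Igf2 had values of -1.11 and -1.23 without passing, and 6 genes fell when adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.347 with an estimated correlation). The imprinted median was -0.12 without replicate number 1 and -0.13 without number 3. The core and linker histone list was higher, with a median of 0.31 over 45 genes. H2ac4 (1.21 ± 0.19), H3c1 (0.75 ± 0.16) and H3c4 (0.82 ± 0.20) rose, and 6 genes rose when adjusted over the list alone. The list mean was higher in 5 of 8 pairs (camera adjusted p = 0.0492; adjusted p = 0.765 with an estimated correlation). Among glycolysis and hypoxia genes, Vegfa (0.72 ± 0.13) and the glucose transporter gene Slc2a1 (0.49 ± 0.11) rose, and 4 of 18 rose when adjusted over the list alone. The glycolysis median was 0.12 (camera adjusted p = 0.0492; adjusted p = 0.53 with an estimated correlation). Epithelial markers had a median of -0.40 over 6 genes, with Krt14 lower (-1.01 ± 0.15) and 3 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.344 with an estimated correlation). The call of the histone list ended without replicate number 3 (median 0.19, adjusted p = 0.795, camera) and with the replicate number as a block (adjusted p = 0.0685, camera), and the call of the epithelial list ended without number 2 (adjusted p = 0.113, camera). For the glycolysis list, camera adjusted p was 0.0602 with the pair block, 0.0685 without replicate number 1 and 0.131 without number 2 (median 0.05). Cytosolic ribosomal protein genes (median -0.19 over 57) and oxidative phosphorylation genes (median -0.17 over 73) had no member past the threshold singly or over the list alone (camera adjusted p = 0.0137 each; adjusted p = 0.765 and 0.789 with an estimated correlation), and their medians were 0.03 and 0.12 without replicate number 1 and -0.40 and -0.45 without number 3. The other 29 of 37 lists had adjusted p of 0.0536 to 0.901 in camera. Among them were DNA repair genes, of which Ddb2 fell (-0.52 ± 0.12), endothelial markers, of which Eng fell (-1.17 ± 0.22), and HMGB1 receptors, of which Thbd fell (-0.75 ± 0.17).

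In cycling cells, the comparison asked what Hmgb1 loss changes in an unsynchronised culture. Uts2b was at least 6.18-fold higher in KO cells (3 Wt and 3 KO arrays), and Asb2, a ubiquitin ligase subunit gene, rose by 2.03 ± 0.25, P2ry14 by 2.02 ± 0.23, Notch4 by 1.95 ± 0.22 and Htr2b by 1.83 ± 0.25. Aqp1 fell by 2.69 ± 0.32 at ILMN_2756486, detected on all 3 KO arrays. It was at least 7.80-fold lower at ILMN_2980661, detected on 1 KO array, and at least 4.16-fold lower at ILMN_2980663, detected on none. Mrgprf fell by 2.61 ± 0.28, Mmp3 by 2.02 ± 0.22, Cyp7b1, which encodes an oxysterol hydroxylase, by 1.85 ± 0.25, and the matrix protein gene Coch by 1.92 ± 0.37. Cxcl5 fell by 1.92 ± 0.35 (adjusted p = 0.0315, limma), with adjusted p = 0.0627 in limma with the pair block and 0.0132 to 0.999 over all alternatives. Other named genes that rose without a block were Gabrb1, Whrn, Fxyd6, Mgll and Srpx2, by 0.99 to 1.53, and Ifi27l2b, at least 2.18-fold higher and detected on no Wt array. The unnamed probes ILMN_2906728 and ILMN_2757617 fell by 3.26 ± 0.59 and 1.98 ± 0.15, and ILMN_2954474 was at least 3.4-fold lower. The replicate number as a block on all 16 arrays joins arrays of number 2 that differ in Eif2s3y and Xist. With this block, the calls of Whrn, Srpx2, the P2ry14 probe ILMN_3154419 and ILMN_2954474 (adjusted p = 0.0513 each, limma), Cxcl5 (0.0536) and Ifi27l2b (0.0742) ended. With that block on the cycling arrays alone, adjusted p in limma was also above the threshold for Htr2b (0.0811), Gabrb1 (0.0739), Fxyd6 (0.0612), Mgll (0.121) and Coch (0.0983). The same held for the Mmp3 probes ILMN_2899041 and ILMN_2753809 (0.0531 and 0.0739, limma adjusted p) and Aqp1 at ILMN_2756486 (0.0767). With the slide as a block, adjusted p in limma was 0.0501 for Gabrb1, Srpx2, Coch and Cxcl5, 0.0579 for ILMN_2906728 and 0.0675 for Ifi27l2b. Limma called 38 probes, 15 higher and 23 lower, each the same way in 3 of 3 pairs. The count was 12 with median scaling (6 higher, 6 lower), 73 with the pair block, 272 without the 2 arrays that stood apart, and 12 to 24 without any 1 of the 6 arrays, lowest without KO_cycling replicate 2.

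Sterol synthesis genes were lower in cycling KO cells as a list (median -0.33 over 21 genes, lower in 3 of 3 pairs; camera adjusted p = 0.000204; adjusted p = 0.865 with an estimated correlation). None passed singly over all probes in limma, where Cyp51, Insig1, Sqle and Srebf2 had values of -0.96, -0.76, -0.80 and -0.50, and 4 fell when adjusted over the list alone. Histone genes were higher (median 0.74 over 45 genes, 3 of 3 pairs; camera adjusted p = 7.65e-07; adjusted p = 0.865 with an estimated correlation), with none past the threshold singly or over the list alone. H2ac4, H2bc18, H3c1 and H2bc4 had values of 0.68 to 0.99. Without Wt_cycling replicate 3 the histone median was 0.32 (adjusted p = 0.0522, camera). Imprinted genes had a median of -0.28 over 18 genes, with Dlk1, Mest, Igf2 and Dio3 at -2.06, -1.45, -1.50 and -0.56, no gene past the threshold over all probes and 2 lower over the list alone (camera adjusted p = 0.0214; adjusted p = 0.865 with an estimated correlation). Camera adjusted p for the imprinted list was 0.209 without Wt_cycling replicate 3 (median -0.13) and 0.064 without KO_cycling replicate 1. The extracellular matrix list had a median of -0.09 over 54 genes, which was 0.12 with median scaling. Col6a2 fell in it (-1.02 ± 0.17), 8 genes were lower and 2 higher over the list alone, and Omd, Mfap4 and Col6a1 had values of -1.15, -1.37 and -0.90 (camera adjusted p = 0.0424; adjusted p = 0.865 with an estimated correlation). Camera adjusted p for the matrix list was 0.24 without Wt_cycling replicate 3 (median -0.01), 0.0503 without Wt_cycling replicate 1 and 0.057 without KO_cycling replicate 1 (median -0.04), and its median was -0.16 without Wt_cycling replicate 2. Of 37 lists, the 30 not called had adjusted p of 0.0729 to 0.956 in camera.

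In G1 cells, where the same question was put to cells held before replication, Cxcl5 fell by 2.38 ± 0.35 (5.19-fold, 3 Wt and 3 KO arrays), as did Sfrp2 (-2.83 ± 0.48) and Smpdl3b, a sphingomyelin phosphodiesterase-like gene (-1.90 ± 0.24). The glutamate transporter gene Slc1a3 fell by 1.66 ± 0.25, the keratin-associated gene Krtap1-5, detected on 1 of 3 KO arrays, was at least 3.18-fold lower, and Hsd17b1, an estradiol-forming enzyme gene detected on no KO array in G1, was at least 1.60-fold lower. Aqp1 fell by 1.91 ± 0.32 to 2.20 ± 0.34 at its 3 probes, and Clec11a and Ecrg4 fell by 2.30 ± 0.43 and 1.71 ± 0.31. The desmosome gene Pkp2 rose by 1.46 ± 0.26, Srpx2 by 1.14 ± 0.17, the neural adhesion gene Ncam1 by 1.14 ± 0.21 and the collagen cross-linking enzyme gene Loxl2 by 1.14 ± 0.22. The transcription factor gene Mycl rose by 1.58 ± 0.29, Plekhg3 by 1.04 ± 0.20 and Tafa5 by 0.93 ± 0.17. Gabrb1 was detected on no Wt array and was at least 1.65-fold higher. The unnamed probe ILMN_1255416 fell by 2.97 ± 0.48. Limma adjusted p for these genes was between 0.00806 and 0.0465 without a block. With the pair block, limma adjusted p was above the threshold for Aqp1 (0.0545 to 0.0737), Clec11a (0.07), Ecrg4 (0.0848), Mycl (0.0678), Ncam1 (0.088), Loxl2 (0.0735), Plekhg3 (0.0744), Tafa5 (0.0678) and the Pkp2 probe ILMN_2665948 (0.0574). As in cycling cells, the replicate number as a block on all 16 arrays joins arrays of number 2 that differ in Eif2s3y and Xist. With this block, limma adjusted p was 0.0587 to 0.0833 for Mycl, Ncam1, Loxl2, Plekhg3, Tafa5, Clec11a, Ecrg4 and the Pkp2 probes ILMN_2637122 and ILMN_2665948. With the slide as a block it was 0.0537 to 0.0574 in limma for the same genes, ILMN_2637122 apart. With the replicate block on the G1 arrays alone, 0 probes passed limma (666 at an unadjusted p under 0.05). Limma called 35 probes, 9 higher and 26 lower, all the same way in 3 of 3 pairs. Median scaling gave 19, of which 0 were higher, the 2 groups fitted alone gave 0 (478 at an unadjusted p under 0.05 in limma), slide 2 alone gave 0 (745 at an unadjusted p under 0.05 in limma), leaving out both arrays that stood apart gave 126, and leaving out 1 of the 6 arrays gave 1 (without Wt_G1 replicate 2) to 43 (without KO_G1 replicate 1).

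As a list, replication genes were lower in G1 KO cells (median -0.46 over 37 genes, lower in 3 of 3 pairs; camera adjusted p = 2.07e-08; adjusted p = 0.21 with an estimated correlation, and 0.0161 in fry). Ung, Tk1, Rfc5 and Pola2 had values of -1.21, -1.06, -0.85 and -0.66, with 0 genes past the threshold over all probes and 4 over the list alone in limma. G2/M genes had a median of -0.47 over 34 genes, lower in 3 of 3 pairs and with no member past the threshold, Nusap1, Ndc80, Kif22 and Cenpa being at -0.55 to -0.85 (camera adjusted p = 1.68e-05; adjusted p = 0.603 with an estimated correlation). Leaving out 1 array gave G2/M medians of -0.66 to -0.27, with -0.27 without Wt_G1 replicate 2 and -0.29 without KO_G1 replicate 1. The replication median was -0.30 without KO_G1 replicate 1. Sterol synthesis genes were higher, with a median of 0.46 over 21 genes and in 3 of 3 pairs. Sc5d, Insig1 and Sqle had values of 1.15, 0.86 and 0.84, and 4 rose over the list alone (camera adjusted p = 0.000114; adjusted p = 0.504 with an estimated correlation). Endothelial markers had a median of -0.71 over 9 genes, with Ly6c1 and Eng at -2.21 and -1.08 and 2 lower over the list alone (camera adjusted p = 0.00685; adjusted p = 0.504 with an estimated correlation). Without KO_G1 replicate 1, the endothelial median was -0.43 (adjusted p = 0.139, camera), and without Wt_G1 replicate 1 it was -0.40.

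Smaller lists in G1 included glycolysis genes (median 0.27 over 18, with Vegfa at 0.89 and 1 higher over the list alone; camera adjusted p = 0.0248; adjusted p = 0.603 with an estimated correlation) and smooth muscle genes (median 0.22 over 20, with Lmod1 at 0.88 and 1 higher over the list alone; camera adjusted p = 0.0189; adjusted p = 0.698 with an estimated correlation). Krt14 fell among epithelial markers (-1.61 ± 0.24; list median -0.50; camera adjusted p = 0.032; adjusted p = 0.504 with an estimated correlation). Genes of the Nrf2 response had a median of -0.24 over 28, with 1 higher and 2 lower over the list alone (camera adjusted p = 0.032; adjusted p = 0.698 with an estimated correlation), and a median of -0.04 without KO_G1 replicate 1 and of -0.46 without KO_G1 replicate 2. The smooth muscle median ran from 0.05 without Wt_G1 replicate 1 to 0.40 without KO_G1 replicate 1 and was 0.10 without KO_G1 replicate 3, and the glycolysis median was 0.14 without Wt_G1 replicate 1. Without Wt_G1 replicate 1, camera adjusted p was 0.158 for glycolysis, 0.308 for smooth muscle and 0.161 for Nrf2, and without KO_G1 replicate 2 it was 0.107 for glycolysis, 0.169 for smooth muscle and 0.17 for epithelial markers. Without KO_G1 replicate 3, camera adjusted p was 0.0817 for glycolysis, 0.305 for smooth muscle and 0.0906 for epithelial markers, which had 0.0727 without Wt_G1 replicate 2 and 0.0695 without Wt_G1 replicate 3. The 26 lists not called had adjusted p of 0.0623 to 0.925 in camera.

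Oxidative phosphorylation and ribosomal protein genes passed camera in opposite directions in these phases, along with the 2 arrays that stood apart. The oxidative phosphorylation list (73 genes) had a median of 0.48 in cycling cells (adjusted p = 0.00112, camera; adjusted p = 0.891 with an estimated correlation) and -0.47 in G1 (adjusted p = 6.68e-06, camera; adjusted p = 0.71 with an estimated correlation). No member passed limma in either phase, over all probes or adjusted over the list alone. Without Wt_cycling replicate 3 and KO_G1 replicate 1 the medians were -0.05 and 0.14, and the G1 list passed camera in that direction (adjusted p = 6.83e-04; adjusted p = 0.361 with an estimated correlation). Cytosolic ribosomal protein genes (57) went from 0.29 and -0.44 to -0.13 and 0.02, and mitochondrial ribosomal protein genes (69) from 0.28 and -0.46 to -0.03 and 0.11. Of these, the cytosolic list in cycling cells and the mitochondrial list in G1 passed camera in the new direction with the preset correlation (adjusted p = 0.0114 and 0.0115). With all arrays, camera adjusted p for these 2 lists was 0.0371 and 0.0424 in cycling cells and 1.2e-05 each in G1. With an estimated correlation adjusted p = 0.891 for both in cycling cells and 0.71 for both in G1. In S cells, which include neither array, the oxidative phosphorylation median was -0.52 and lower in 2 of 2 pairs (adjusted p = 7.02e-06, camera; adjusted p = 0.701 with an estimated correlation). The cytosolic ribosomal median there was -0.36, also in 2 of 2 pairs (adjusted p = 0.000201, camera; adjusted p = 0.701 with an estimated correlation).

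**Figure D3:**
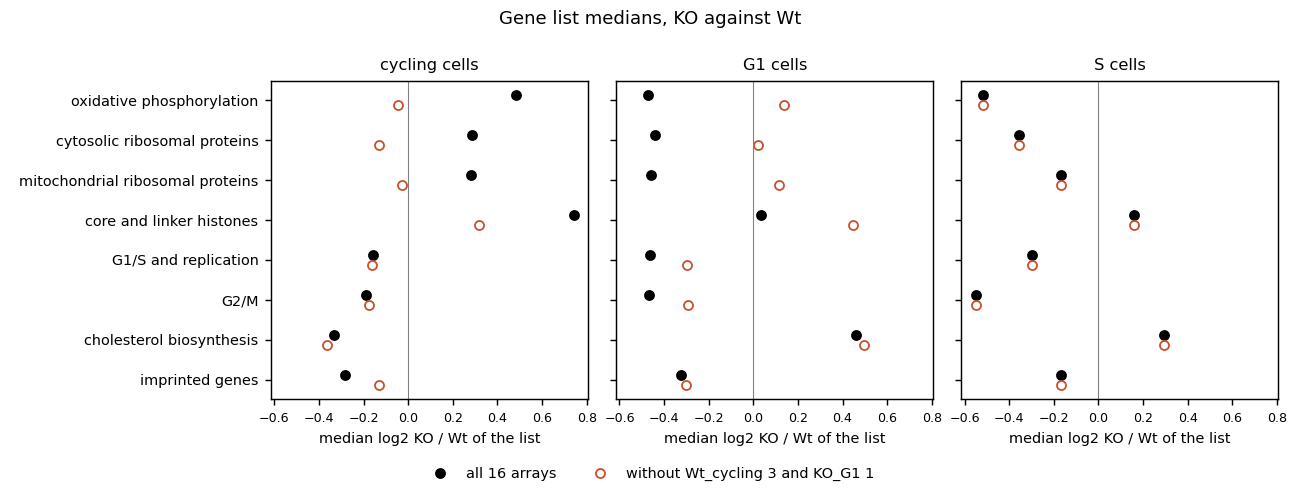
Median log2 difference, KO against Wt, of 8 gene lists in cycling, G1 and S cells, with all 16 arrays (filled points) and without Wt_cycling replicate 3 and KO_G1 replicate 1 (open points). Without these arrays the oxidative phosphorylation median went from 0.48 to -0.05 in cycling cells and from -0.47 to 0.14 in G1.

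In S cells, the question was what Hmgb1 loss changes during replication. Cxcl5 fell by 3.14 ± 0.42 (8.83-fold, 2 Wt and 2 KO arrays), the chemokine gene Cxcl15 by 2.84 ± 0.39, the corneodesmosin gene Cdsn by 2.89 ± 0.42 and Mmp3 by 2.42 ± 0.36 to 2.62 ± 0.36 at its 3 probes. Aqp1 fell by 2.20 ± 0.39 to 2.61 ± 0.41 at its 3 probes. Vip, which encodes a vasoactive neuropeptide, and Uts2b were detected on no Wt array in S and were at least 3.78-fold and 3.46-fold higher. Loxl2 rose by 1.53 ± 0.26 and Srpx2 by 1.41 ± 0.21 and 1.35 ± 0.21 at its probes. The unnamed probe ILMN_2735350 fell by 2.27 ± 0.38, and ILMN_1253772, detected on neither KO array, was at least 7.15-fold lower. Limma called 28 probes, 5 higher and 23 lower, each the same way in 2 of 2 pairs. The 2 arrays of a group correlated at 0.995 in Wt and 0.994 in KO, and deviations of the same number at 0.0644. The arrays therefore do not show that the 2 S pairs are independent replicates. With the 2 S groups fitted alone, the spread came from these arrays and limma called 1995 probes. With the replicate number as a block in that fit it called 1409. With the pair block, adjusted p in limma was 0.0654 to 0.11 for Aqp1, 0.0607 for Loxl2 and 0.0512 for the Srpx2 probe ILMN_2818294. With the replicate number as a block on all 16 arrays, which has the limit given for cycling cells, it was 0.0626 in limma for Loxl2. Aqp1 at ILMN_2756486 had the same value with this block and 0.0511 with the slide as a block. The count was 11 with median scaling, 0 to 2 without 1 of the 4 arrays (0 without Wt_S replicate 2 or KO_S replicate 1, with 299 and 311 at an unadjusted p under 0.05 in limma) and 486 without the 2 arrays that stood apart in other phases.

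Inflammatory genes were lower as a list in S cells. The NF-kB and inflammation list had a median of -0.35 over 36 genes, lower in 2 of 2 pairs. In it Mmp3 and Cxcl5 were past the threshold, with 3 lower over the list alone, and Traf1 and Serpina3n at -0.81 and -0.88 (camera adjusted p = 7.02e-06; adjusted p = 0.203 with an estimated correlation). Interferon response genes had a median of -0.24 over 40 genes and no member past the threshold. Ccl5, Gbp2, Irf1 and Cxcl10 were at -1.19, -0.99, -0.51 and -0.88 (camera adjusted p = 0.00362; adjusted p = 0.329 with an estimated correlation). G2/M genes had a median of -0.55 (camera adjusted p = 7.25e-11; adjusted p = 0.211 with an estimated correlation) and G1/S genes -0.30 (camera adjusted p = 6.83e-07; adjusted p = 0.203 with an estimated correlation). Neither list had a member past the threshold, over all probes or over the list alone. Macrophage and blood markers had a median of -0.73 over 22 genes, none past the threshold, with Fcgr2b and Pf4 at -1.54 and -2.04 (camera adjusted p = 0.00044; adjusted p = 0.665 with an estimated correlation), and glycolysis genes one of 0.26 over 18 genes, with Vegfa, Slc2a1 and Hk2 at 0.83, 0.63 and 0.61 and none past the threshold (camera adjusted p = 0.00102; adjusted p = 0.211 with an estimated correlation). The quiescence and growth arrest list held Igfbp5, which fell by 1.93 ± 0.31, with a list median of -0.05 (camera adjusted p = 0.0345; adjusted p = 0.449 with an estimated correlation). Further lists called by camera were imprinted genes (median -0.17), senescence genes (-0.19), the epithelial (-0.52), endothelial (-0.60), skeletal muscle (-0.63) and neural (0.21) markers, and glucocorticoid receptor targets (-0.22). Their adjusted p was 0.00106 to 0.0498 in camera, and with an estimated correlation adjusted p = 0.211 to 0.319. The imprinted median was -0.09 without Wt_S replicate 1, and the quiescence median -0.10 without KO_S replicate 1. The call of the neural list ended with the pair block (adjusted p = 0.12, camera), without Wt_S replicate 1 (0.0579) and without KO_S replicate 1 (0.0823). The glucocorticoid call ended without Wt_S replicate 2, KO_S replicate 1 or KO_S replicate 2 (adjusted p of 0.12, 0.0572 and 0.0769 in camera). With the 2 S groups fitted alone and the replicate number as a block, camera adjusted p was 0.0704 for endothelial, 0.0736 for epithelial, 0.0684 for senescence, 0.146 for quiescence, 0.246 for neural and 0.0554 for glucocorticoid genes. Without the 2 arrays that stood apart in other phases, camera adjusted p was 0.0626 to 0.103 for the quiescence list and for these further lists other than senescence. The 21 lists not called had adjusted p of 0.0683 to 0.939 in camera.

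Whether the effect of Hmgb1 loss depends on the phase was tested as a difference of differences. Between G1 and cycling cells, sterol synthesis genes shifted as a list: their KO against Wt difference was higher in G1 by a median of 0.83 over 21 genes, with Cyp51, Insig1, Sqle and Srebf2 at 1.58 ± 0.31, 1.62 ± 0.32, 1.64 ± 0.35 and 0.93 ± 0.23. No sterol gene passed limma over all probes and 6 did over the list alone (camera adjusted p = 7.37e-08; adjusted p = 0.36 with an estimated correlation, and 0.0804 in fry). By limma, 1 probe passed, ILMN_2757617, which has no symbol, and 1140 had an unadjusted p under 0.05. Its difference was 1.92 ± 0.22 (adjusted p = 0.00657, limma), with 0 calls by limma with the pair block (1678 at an unadjusted p under 0.05) or median scaling (811), 0 without any 1 replicate number (379 to 689), and 5 calls without the 2 arrays that stood apart. Spock3, Ankrd13c, Ing4, Igsf9 and Pi16 were among the smallest p without passing (2.25, 1.77, -1.27, -1.73 and -1.23). Oxidative phosphorylation, histone, ribosomal and general transcription lists, with medians of -0.95 to -0.28 and camera calls here, changed sign without the 2 arrays that stood apart. In the new direction, oxidative phosphorylation (0.18), mitochondrial ribosomal (0.14) and cytosolic ribosomal genes (0.12) passed camera without these arrays (adjusted p = 9.24e-04, 0.0138 and 0.022). With an estimated correlation and without these arrays, adjusted p = 0.296, 0.727 and 0.29 in camera. Camera also called the G1/S (-0.35), matrix (0.31, and -0.09 with median scaling), macrophage (-1.12), endothelial (-0.85), heat shock (0.45) and glycolysis (0.26, and -0.06 with median scaling) lists, with adjusted p of 0.00218 to 0.0433. With an estimated correlation adjusted p = 0.717 for each of these 11 lists, the sterol list apart. Without the 2 arrays that stood apart, the calls of the G1/S, matrix, endothelial, heat shock and glycolysis lists ended (adjusted p of 0.078 to 0.431 in camera). Without replicate number 1, camera adjusted p was 0.274 for macrophage genes (median -0.49) and 0.193 for endothelial (-0.36), heat shock (0.18) and glycolysis genes (0.12), and 0.312 for general transcription genes (-0.18). Without number 3 the macrophage median was -1.77, and without number 2 the glycolysis median was 0.42 and the oxidative phosphorylation median -1.53.

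Between S and G1 cells, the difference for the NF-kB and inflammation list was lower in S by a median of -0.26 over 36 genes, with Serpina3n, Mmp3, Traf1 and Mmp13 at -1.67, -1.32, -0.62 and -1.19 and 2 genes past the threshold over the list alone (camera adjusted p = 1.98e-05; adjusted p = 0.266 with an estimated correlation). Its median was -0.49 without replicate number 1. The p53 target list had a median of -0.15, with Eda2r and Pmaip1 at -1.02 and -1.24 (adjusted p = 0.0367, camera; adjusted p = 0.941 with an estimated correlation), and without replicate number 1 its adjusted p was 0.86 in camera, while its median was -0.29 without number 2. The matrix list (-0.13, with a sign change under median scaling) and the mitochondrial ribosomal list (0.20) were also called by camera (adjusted p = 0.0415 and 0.0383; adjusted p = 0.941 and 0.998 with an estimated correlation), and without replicate number 1 camera gave an adjusted p of 0.349 and 0.131, the latter with a median of -0.28, against 0.44 without number 2 and 0.48 without number 3. Limma called 0 probes, with 184 at an unadjusted p under 0.05, and 105 without the 2 arrays that stood apart. Mapk12, Adm, Fbxo32, Serpina3n and Myh11 had values of 1.17, 1.68, -1.36, -1.67 and -1.74.

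G1-synchronised cells were compared with cycling cells to describe the synchronised state. Several of the genes that rose most were detected on few cycling arrays, so their folds are lower limits. Fibcd1, which encodes a chitin-binding membrane protein, was at least 58.2-fold higher in G1, the proteoglycan gene Lum at least 48.3-fold and Cxcl15 at least 19.3-fold. Serpinb2 was at least 17.6-fold higher, the growth factor-binding gene Igfbp3 at least 13.8-fold and Fgl2 at least 8.31-fold. The microfibril gene Mfap4 rose by 4.19 ± 0.21 and Itm2a by 3.85 ± 0.22 (6 cycling and 6 G1 arrays, the same way for 3 replicate numbers in each genotype). The granzyme gene Gzme was at least 4.67-fold lower and the potassium channel subunit gene Kcnmb1 at least 4.95-fold. The granzyme gene Gzmd fell by 2.67 ± 0.29, Ccn5 by 2.50 ± 0.48, the actin gene Acta1 by 2.24 ± 0.34 and the clock-controlled gene Dbp fell too (-2.15 ± 0.26). Vip was detected on no G1 array and was at least 2.99-fold lower. Adjusted p in limma was 7.76e-11 for Fibcd1 and at most 0.00269 for the others. Limma called 2394 probes, 1174 higher and 1220 lower, and 1772 of them moved the same way for all 3 replicate numbers in both genotypes. A replicate number need not be the same line in both phases, since number 2 had Eif2s3y detected in cycling cells and Xist in G1. All cycling arrays and 1 of the 3 G1 pairs lay on slide 1, and within slide 1 the count was 766, with the slide as a block 765, and with the slide and replicate number within genotype as blocks 260. Within slide 1, adjusted p in limma was 0.0971 for Acta1 and 0.054 for the Gzme probe ILMN_1224204. With the slide and replicate number within genotype as blocks, the calls of Ccn5 (-2.06), Gzmd (-1.86), Acta1 (-0.94) and that Gzme probe (-1.24) ended (adjusted p of 0.138, 0.0515, 0.0704 and 0.0744 in limma). Without replicate number 2 the count was 132, and without the 2 arrays that stood apart 4183.

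Replication genes fell in G1, where 27 of 37 passed, and 32 over the list alone. Mcm2 was at -1.42 ± 0.15, Mcm5 at -0.98 ± 0.11, Cdc6 at -1.24 ± 0.16 and Tk1 at -1.59 ± 0.20. The list median was -0.85 (camera adjusted p = 3.26e-15; adjusted p = 0.0318 with an estimated correlation, so the call held) and -0.73 within slide 1. Of 34 G2/M genes, 22 fell and 30 did over the list alone, Dlgap5, Tpx2, Nusap1 and Ndc80 by 1.47, 1.09, 0.76 and 1.07 (median -0.90, and -0.72 within slide 1; camera adjusted p = 2.81e-11; adjusted p = 0.186 with an estimated correlation). Inflammatory genes rose, 16 of 36 with 2 lower and 18 with 3 lower over the list alone. Mmp3 rose by 3.13, Serpina3n by 2.51, Mmp13 by 2.49 and Ccl8 by 2.14 (median 0.71, and 0.82 within slide 1; camera adjusted p = 8.18e-06; adjusted p = 0.0945 with an estimated correlation). Of 54 matrix genes, 22 rose and 2 fell, with 23 and 4 over the list alone. Tgfbi (2.68 ± 0.14) and Timp3 (1.92 ± 0.15) were among those that rose (median 0.26, and 0.24 within slide 1; camera adjusted p = 2.24e-05; adjusted p = 0.183 with an estimated correlation). Immediate early genes Fosl1, Zfp36, Dusp6 and Egr2 rose by 1.26, 1.11, 0.93 and 1.13, with 10 of 26 higher and 13 over the list alone (list median 0.42, and 0.49 within slide 1; camera adjusted p = 3.87e-05; adjusted p = 0.186 with an estimated correlation). Of 32 DNA repair genes, 10 fell and 13 did over the list alone, among them Apex1, Xrcc6, Parp1 and Fancd2 by 1.08, 0.68, 0.75 and 0.93 (median -0.38, and -0.34 within slide 1; camera adjusted p = 0.000236; adjusted p = 0.0538 with an estimated correlation). Further lists called by camera were Hox genes (-0.58), senescence genes (0.39), TGF-beta targets (0.32), HMGB1 receptors (0.47), imprinted genes (0.26), glycolysis genes (-0.63), mitochondrial ribosomal protein genes (-0.23), smooth muscle genes (-0.34) and quiescence genes (0.25). Their adjusted p was 0.00282 to 0.0367 in camera, and with an estimated correlation adjusted p = 0.34 to 0.869. Among their genes, Cdkn1c rose by 2.93 ± 0.32, Il1r1 by 1.44 ± 0.24 and Cxcr4 by 1.47 ± 0.29. Within slide 1, camera adjusted p was 0.0879 for Hox genes, HMGB1 receptors and imprinted genes, 0.285 for smooth muscle genes and 0.294 for quiescence genes, and the mitochondrial ribosomal median was 0.03. Without replicate number 1, camera adjusted p was 0.26 for quiescence genes, 0.141 for HMGB1 receptors and for smooth muscle genes, 0.17 for imprinted genes and 0.0801 for Hox genes, and without number 3 it was 0.068 for glycolysis genes and 0.107 for senescence genes. With the slide and replicate number within genotype as blocks, it was 0.0888 for TGF-beta targets in camera. The TGF-beta median was 0.21, 0.15 and 0.49 without number 1, 2 and 3. Without number 1 the Hox, imprinted and mitochondrial ribosomal medians were -0.24, 0.12 and 0.18, and without number 3 the quiescence and mitochondrial ribosomal medians were 0.41 and -0.56.

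**Figure D4:**
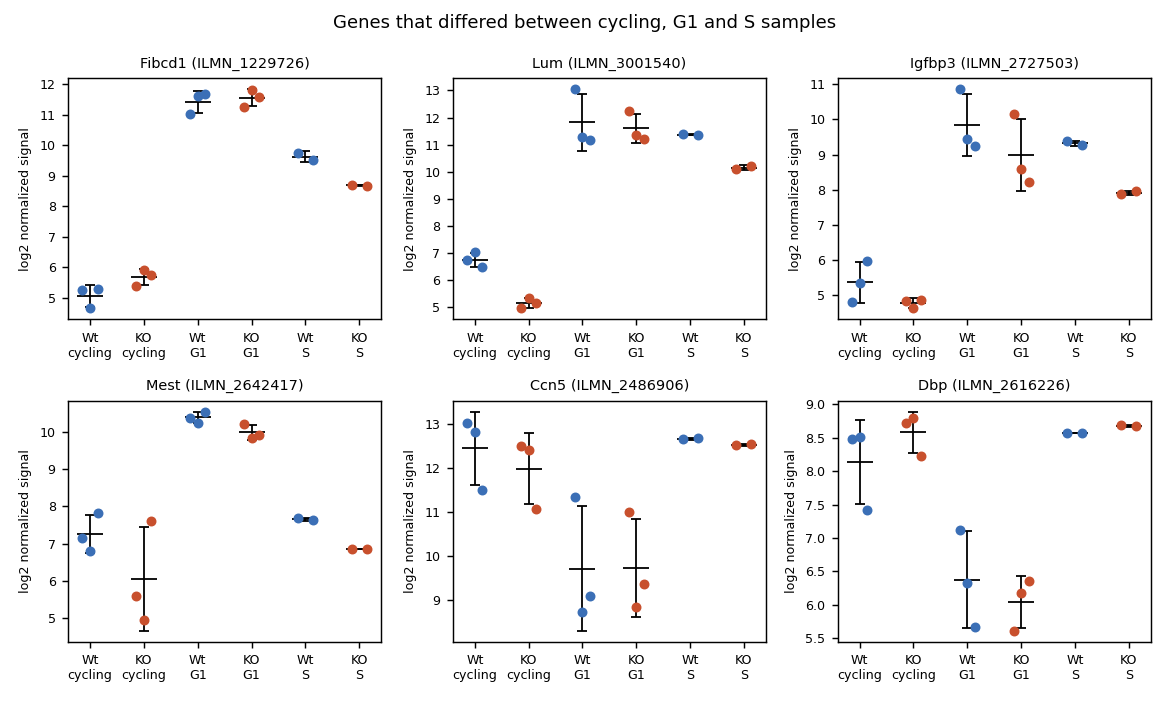
Normalized log2 signal of 6 genes that differed between phases, on each array, by genotype and phase; bars are the group mean and standard deviation. Fibcd1, Lum and Igfbp3 were higher in G1 than in cycling cells, Mest was lower in S than in G1, and Ccn5 and Dbp were lower in G1 than in cycling and S cells.

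S-synchronised cells were compared with G1 cells for the same purpose. The imprinted gene Mest fell in S by 2.49 ± 0.34 to 2.93 ± 0.39 at its 3 probes, and the membrane lectin gene Chodl (-3.70 ± 0.58), Fibcd1 (-2.34 ± 0.19), the calcium channel subunit gene Cacna2d1 (-2.10 ± 0.24) and Abhd1 (-2.10 ± 0.37) fell too (4 S and 6 G1 arrays, the same way for both shared replicate numbers in each genotype). Dbp rose by 2.42 ± 0.29, the quinone reductase gene Nqo1 by 2.30 ± 0.27, Ccn5 by 2.87 ± 0.54, Zfp365 by 2.44 ± 0.46 and Ccng2, a cyclin gene linked to growth arrest, by 2.50 ± 0.54. On the G1 arrays, Ccn5, Ccng2 and Zfp365 were higher and Abhd1 was lower where Eif2s3y was detected. With its detection as a block the first 3 rose by 1.33 to 1.68, Abhd1 was at -1.60 and all 4 kept their calls in limma. Hpgd, Adh7, Sprr2k and Fbxl13 also passed. Hpgd and Adh7, detected on 2 and 1 of 6 G1 arrays, were at least 6.94-fold and 4.35-fold higher, Sprr2k rose by 2.71 ± 0.69 and Fbxl13 fell by 2.63 ± 0.62. On the G1 arrays with Eif2s3y detected, Hpgd was at 9.08 in Wt and 8.41 in KO, against 9.27 to 9.56 in S. Adh7 was there at 7.72 and 5.71, against 7.55 to 8.62 in S. These 2 limits therefore hold for the groups as measured, not for the phase alone. With Eif2s3y detection as a block, Hpgd was at 1.22 (adjusted p = 0.0612, limma), Sprr2k at 2.02 (adjusted p = 0.113, limma) and Fbxl13 at -1.49 (adjusted p = 0.0657, limma), and Adh7 was at 1.12 (adjusted p = 0.0363, limma). With the replicate number within genotype as a block, adjusted p in limma was 0.0594, 0.0608 and 0.0703 for Hpgd, Adh7 and Sprr2k. With the slide as a block, adjusted p in limma was 0.105 for Hpgd, 0.0985 for Adh7 and 0.0589 for Fbxl13. Within slide 2, adjusted p in limma was 0.117 for Ccn5, 0.123 for Ccng2, 0.118 for Zfp365 and Abhd1, 0.0634 for Nqo1, 0.252 for Hpgd, 0.13 for Adh7 and 0.228 for Fbxl13. Limma called 1375 probes, 691 higher and 684 lower, and with median scaling 876 (689 higher, 187 lower). The count was 845 with the slide as a block, 26 within slide 2, 672 with the replicate number within genotype as a block, 0 without replicate number 2 (928 at an unadjusted p under 0.05 in limma) and 4281 without the 2 arrays that stood apart.

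Replication genes rose in S, where 22 of 37 rose and 1 fell, with 30 and 1 over the list alone. Mcm5, Pole, Ccne2 and Mcm7 rose by 0.88, 1.15, 1.19 and 0.95 (median 0.73, and 0.81 within slide 2; camera adjusted p = 1.34e-12; adjusted p = 0.0608 with an estimated correlation). Targets of p53 rose, 7 of 23 and 8 over the list alone, with Ei24, Trp53inp1, Fas and Ddit4l at 1.06, 1.46, 1.20 and 1.45 (median 0.42, and 0.34 within slide 2; camera adjusted p = 0.00266; adjusted p = 0.818 with an estimated correlation). Sterol genes fell, 5 of 21 and 7 over the list alone. Idi1, Hsd17b7, Stard4 and Nsdhl were at -1.32, -0.65, -0.81 and -1.11 (median -0.43, and -0.35 within slide 2; camera adjusted p = 0.000252; adjusted p = 0.738 with an estimated correlation). Of 21 Hox genes, 6 rose, with 7 higher and 2 lower over the list alone, including Hoxd8 (1.29 ± 0.19) and Hoxc10 (1.27 ± 0.24) (median 0.45, and 0.57 within slide 2; camera adjusted p = 0.0311; adjusted p = 0.818 with an estimated correlation). The Hox list had an adjusted p of 0.315 in camera without replicate number 1 (median 0.29) and a median of 0.68 without number 2. Macrophage and blood markers had a median of 1.07 over 22 genes, of which Itgb2 rose (0.75 ± 0.19) and C1qa, Lyz2 and C1qc were at 2.10, 1.38 and 2.12 (camera adjusted p = 0.000304; adjusted p = 0.818 with an estimated correlation). Eif2s3y was detected on 4 of 4 S arrays and 2 of 6 G1 arrays, and with its detection as a block the macrophage median was 0.08, while without replicate number 2 it was 0.48. Immediate early genes had a median of -0.37 over 26, with 3 higher and 6 lower (camera adjusted p = 0.00733; adjusted p = 0.818 with an estimated correlation). With Eif2s3y detection as a block, the immediate early median was -0.22 and the call ended (adjusted p = 0.127, camera). Of the 762 probes past the threshold in both phase comparisons, 749 moved in opposite directions; both comparisons share the G1 arrays.

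**Figure D5:**
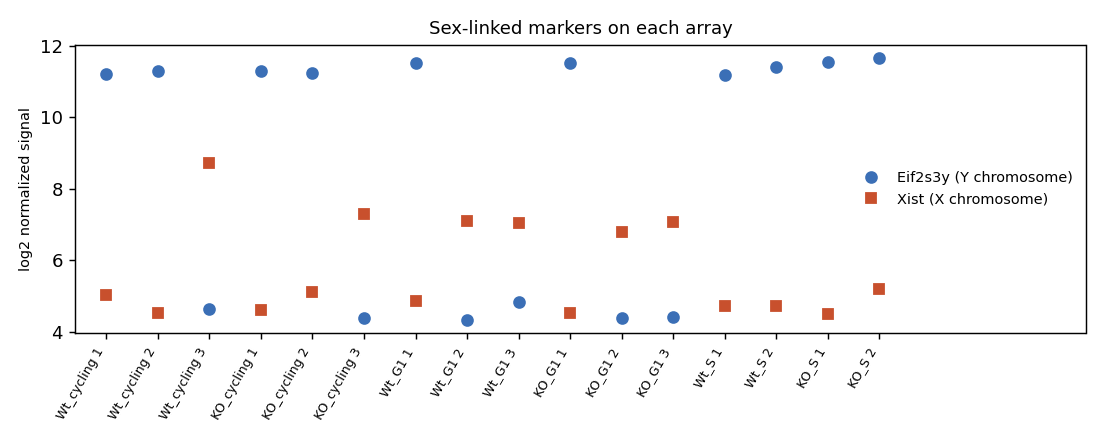
Normalized log2 signal of Eif2s3y (circles) and Xist (squares) on each of the 16 arrays. Eif2s3y was detected on 10 arrays and Xist on the other 6, and no array had both.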

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

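The tests that left out the arrays Wt_cycling replicate 3 and KO_G1 replicate 1, that used the other pairs or median scaling for the oxidative phosphorylation list, that compared Eif2s3y and Xist or number 2 between phases, that exchanged whole replicate numbers, and that used Eif2s3y detection as a block were chosen after the results were seen.

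Probe ILMN_2757617, which has no symbol, was singled out because its KO against Wt difference was larger in cycling cells than in G1 cells. The difference of the differences was 1.92 ± 0.22 log2 units (adjusted p = 0.00657, limma). KO against Wt was -1.98 in cycling cells, -0.06 in G1 and -0.97 in S, and the probe was detected on all 16 arrays. Cycling KO arrays lay between 11.6 and 11.7 on the log2 scale and cycling Wt arrays between 13.5 and 13.6. The call ended with the pair block (adjusted p = 0.159, limma) and with median scaling, where the difference was 1.42. Over all alternatives adjusted p was 0.000313 to 0.776 in limma. No explanation was tested, since the probe's gene is not given.

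Oxidative phosphorylation genes as a list were higher in KO cells when cycling (median 0.48) and lower in G1 (-0.47). Without Wt_cycling replicate 3 and KO_G1 replicate 1, the difference between these medians was 0.18, against -0.95 with all arrays. In 0 of the 4 other pairs did the list mean go the way of its phase, so the 2 directions rest on the pairs with these arrays. The 2 arrays were singled out partly by their mean of this list. Among the 4 other pairs, Eif2s3y detection goes with the phase. These pairs therefore cannot decide whether Hmgb1 loss acts in these directions. These pairs had -0.10 and -0.03 in cycling cells and 0.12 and 0.12 in G1. Without the 2 arrays the list passed camera the other way round (KO effect in G1 against cycling 0.18, adjusted p = 9.24e-04, and 0.296 with an estimated correlation), so a smaller effect that differs between the phases stays open. With median scaling the difference was -1.31, which argues against quantile normalization as the source. The 2 arrays are a candidate explanation, while what sets them apart, RNA quality or the cells, stays open.

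Replicate number 2 had Eif2s3y detected on its cycling and S arrays and Xist on its G1 arrays, in both genotypes. A single mislabelled array would split a pair, and 0 of the 8 Wt and KO pairs were split. Cells of both kinds on 1 array would give both signals, and 0 arrays of number 2 had Eif2s3y and Xist both detected. The Y-linked gene Uty was detected with Xist on both G1 arrays of number 2, at 5.67 and 5.45, near the lowest values of detected probes, while Kdm5d was not. Uty was also detected with Xist on KO_G1 replicate 3 (5.74) and not detected on Wt_cycling replicate 2, so its signal is not particular to number 2 in G1. On the G1 arrays of number 2, Eif2s3y was at 4.33 and 4.39, against 11.2 or more where it was detected. This argues against a mixture as the source of the change of signal, while a trace of such cells is not excluded. Whether the numbers name different lines in different phases was tested on number 2 minus the array of its group with the same signal. This difference correlated at -0.0065 between cycling and G1 cells in the genotype with the higher value. Between cycling and S cells, where number 2 kept its signal, it correlated at 0.042 and -0.0051, so the test could not recognise a line. The Eif2s3y levels of number 2 were 11.3 in Wt and 11.2 in KO in cycling cells, against 4.33 and 4.39 in G1. With Xist detected in G1 alone, they argue against number 2 naming the same line in cycling and G1 cells. Of the 3 pairs per phase, 2 had Eif2s3y detected in cycling cells and 1 in G1. If a line keeps its signal, no renumbering of the same 3 pairs gives both counts. These counts argue against the same 3 pairs of lines in both phases. For numbers 1 and 3 taken singly the question stays open. For number 2, the replicate number as a block across phases then joins different lines. The description gives no sex for the embryos.

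The G1 against cycling difference covers 2394 probes by limma, with most G1 arrays on another slide. Within slide 1, the median change of these probes in the direction found with all arrays was 0.72. The probes were chosen in a fit that held the slide 1 arrays, so part of this agreement is built in. Both G1 arrays of slide 1 had Xist detected, while most of its cycling arrays had Eif2s3y. The count was 765 with the slide as a block and 703 with Eif2s3y detection as well. With the slide and replicate number within genotype as blocks it was 260. A difference between slides therefore does not account for all of the calls, while its share stays open. With Eif2s3y detection alone as a block, 92.8% of the 2394 were still called. The G1/S and replication list had a median of -0.73 within slide 1, which is consistent with fewer cells in S, G2 and M among the G1 samples. The time in culture and the synchronisation treatment go with the phase and stay open.

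Other splits of the arrays were counted for each comparison with 3 or more arrays in a group. For the KO against Wt difference averaged over phases, 1 of 100 splits, the real one, called 249 probes or more and the highest other called 50. Splits that part every pair, as the real one does, called at most 19 in 100 draws. Both take the arrays of different phases as separate, and on that footing chance can be excluded. If a number is 1 litter in every phase, only 4 splits exchange the genotype of whole numbers, too few for a share under 0.05. The real one called 249 and the highest other 0, and the fit of 3 values against 3 called 4. In cycling cells the real split called 38 probes and the highest other 0, and in G1 cells 35 and 1, with 10 splits each, too few for a share under 0.05. G1 against cycling called 2394 against 873 for the highest other, with 1 of 100 splits as large. These splits take the Wt and KO arrays of a pair as separate, and only on that footing can chance be excluded. Whole pairs allow too few splits for a share under 0.05. The split with 873 was the real one with KO_cycling replicate 3 and KO_G1 replicate 1 exchanged, so it still holds much of the phase difference. It also set Wt_cycling replicate 3 and 5 of the 6 arrays with Eif2s3y detected against the rest. S against G1 called 1375, and 2 of 100 splits called as many. The other one called 2157 and set all arrays with Eif2s3y detected against the rest, which points to a structure of the samples. That split keeps the pairs whole, while others break them. Whole pairs allow too few splits for a share under 0.05, so chance cannot be excluded for S against G1. With Eif2s3y detection as a block, S against G1 called 1211 probes, of which 860 were among the 1375. With Eif2s3y detection as a block, the S against G1 lists of macrophage and immediate early genes lost their calls while the G1/S list kept it. For the difference of KO effects between G1 and cycling, 10 of 100 splits called 1 probe or more. The highest, with 2394, exchanges the phases within 1 genotype and so measures the phase difference. Other splits that exchange unequal numbers of arrays in the genotypes can carry part of it. This share therefore cannot decide whether the call arose by chance.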

How the results depend on the processing

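The settings that left out Wt_cycling replicate 3 and KO_G1 replicate 1 or their pairs, that used detection of Eif2s3y as a block or averaged arrays by it, that used a block for each pair within its phase, or that kept to 1 slide were chosen after the data were seen. All others were planned. Results are given in the order cycling, G1, S, averaged KO against Wt, then the KO effect in G1 against cycling and in S against G1, then G1 against cycling and S against G1. Where nothing else is said, the cause was not tested. The alternatives planned for the level of Hmgb1 were not run, since its probe was at background. Signal over background limits the folds of probes detected in 1 group alone.

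No named gene reversed its direction. The rule named the genes of the KO and phase comparisons for large changes in the same direction in every pair or replicate number. A reversal was therefore unlikely from the outset. Of the named results under all alternatives, 349 were on the same side of the threshold and 97 were not for averaged KO against Wt, 346 and 149 in cycling cells, 224 and 230 in G1, 214 and 99 in S, 258 and 17 for G1 against cycling, and 218 and 60 for S against G1. With the preset correlation, the G1/S, G2/M and imprinted lists kept their camera call in the alternatives of processing, blocks and arrays of the averaged comparison, but not with an estimated correlation, and in fry the G1/S list alone of these 3 was called. Their medians were -0.31 to -0.20, -0.46 to -0.30 and -0.29 to -0.10.

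Median scaling gave 12, 19, 11 and 150 probes for KO against Wt, 0 for the KO effect in G1 against cycling (811 at an unadjusted p under 0.05 in limma), 1559 for G1 against cycling and 876 for S against G1. The authors' table gave 2 probes for the KO effect in G1 against cycling and 1 for S against G1. No normexp correction gave 1 for the latter. Only probes detected on all 16 arrays gave 25 in cycling and 17 in S cells, with fewer probes tested. The slide as a block gave 22 in cycling cells, 765 for G1 against cycling and 845 for S against G1.

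With pairing, the replicate block on all 16 arrays gave 22 in cycling cells, of which 20 were also called without it, and with the line as a random block 518 averaged over phases. The replicate number within genotype as a fixed block, planned as the line, gave 0 for the KO effect in G1 against cycling (997 at an unadjusted p under 0.05 in limma) and 672 for S against G1, and with the slide as well 260 for G1 against cycling and 705 for S against G1. The 2 groups alone gave 8, 0 and 1995 in cycling, G1 and S cells, and with the replicate block 21, 0 and 1409; in G1, 478 and 666 had an unadjusted p under 0.05 in limma. The spread then comes from fewer arrays. In S these were 2 arrays per group, which correlated at 0.995 in Wt and 0.994 in KO. They are not shown to be independent replicates, so the higher S counts need not mean more changed genes. The block for each pair within its phase gave 73 in cycling cells, 399 averaged and 0 for the KO effect in G1 against cycling (1678 at an unadjusted p under 0.05 in limma). The mean of cycling and G1 per replicate number, 3 values against 3, gave 4. It joins arrays of number 2 that differ in Eif2s3y and Xist, so these values need not be 3 lines each.

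Leaving out 1 array gave 12 to 24 in cycling cells, 1 to 43 in G1 and 0 to 2 in S (0 without Wt_S replicate 2 or KO_S replicate 1, where limma had 299 and 311 at an unadjusted p under 0.05), where the lone array left is assumed to vary like the other groups. Leaving out 1 replicate number gave 0 to 177 averaged (0 without number 2, with 336 at an unadjusted p under 0.05 in limma), 0 to 0 for the KO effect in G1 against cycling and 0 to 0 in S against G1, 132 to 1821 for G1 against cycling (132 without number 2) and 0 to 867 for S against G1 (0 without number 2, with 928 at an unadjusted p under 0.05 in limma).

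Without Wt_cycling replicate 3 and KO_G1 replicate 1 the counts were 272, 126, 486, 1184, 5, 105, 4183 and 4281. Without their pairs they were 1181, 501, 1482, 2351, 218, 387, 5255 and 5910. Without the pairs, all cycling and S arrays left had Eif2s3y detected and all G1 arrays left had Xist detected. Differences between G1 and another phase then cannot be told apart from this signal. Without the 2 arrays alone, Wt and KO differed in how many arrays had Eif2s3y detected, in cycling cells and in G1. The S groups hold neither array, and their list medians did not change, so their count moved through the estimate of the spread, which all arrays share. Eif2s3y detection as a block gave 97, 82, 48 and 423 for KO against Wt and 2 for the KO effect in G1 against cycling, and with the slide as well 703 for G1 against cycling. Averaging arrays of 1 group by it gave 0, 0, 0 and 0 for KO against Wt, 0 for the KO effect in G1 against cycling, 126 for G1 against cycling and 0 for S against G1, from fewer values. In limma, unadjusted p was under 0.05 for 236, 387, 79, 418, 184 and 888 probes where the count was 0. Within slide 2 the G1 count was 0 (745 at an unadjusted p under 0.05 in limma) and the S against G1 count 26, and within slide 1 the G1 against cycling count was 766.

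For the averaged lists, camera called 0 of 37 with an estimated correlation and fry called 2, the G1/S and epithelial lists, where camera with the preset correlation called 8.

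Lists called by camera moved to the other direction in these cases. With median scaling, the matrix median was 0.119 in cycling cells, and for the KO effect in G1 against cycling the extracellular matrix and glycolysis medians were -0.0873 and -0.0551. For the KO effect in S against G1 the matrix median was 0.0015 with median scaling and 0.0108 without both arrays that stood apart. In cycling cells, leaving out 1 array gave -0.129 (without Wt_cycling replicate 3) to 0.521 for cytosolic ribosomal, -0.0287 to 0.459 for mitochondrial ribosomal and -0.0454 to 0.801 for oxidative phosphorylation genes. Leaving out both arrays that stood apart gave -0.129, -0.0287 and -0.0454, and both pairs -0.0929, -0.0168 and -0.0737. In G1, leaving out 1 array gave -0.772 to 0.113 (without KO_G1 replicate 1) for mitochondrial ribosomal and -0.788 to 0.139 for oxidative phosphorylation genes, with 0.0216 for cytosolic ribosomal genes without KO_G1 replicate 1. Without both arrays the cytosolic, mitochondrial and oxidative phosphorylation medians in G1 were 0.0216, 0.113 and 0.139, and without both pairs 0.0126, 0.0566 and 0.138, with Nrf2 genes at 0.0252. Averaged over phases, leaving out 1 replicate number gave -0.397 to 0.0318 (without replicate 1) for cytosolic ribosomal and -0.454 to 0.119 for oxidative phosphorylation genes. For the KO effect in G1 against cycling without both arrays, histones had 0.0962, cytosolic ribosomal 0.122, mitochondrial ribosomal 0.144, oxidative phosphorylation 0.178 and general transcription genes 0.081, and without both pairs the last 4 had 0.12, 0.0174, 0.211 and 0.0086. For the KO effect in S against G1, mitochondrial ribosomal genes had -0.277 (without replicate 1) to 0.475, -0.332 without both arrays and -0.277 without both pairs. For G1 against cycling the same list had 0.034 with the slide as a block and within slide 1, 0.369 with the replicate number within genotype and the slide as blocks (replicate block), and -0.562 to 0.181 (without replicate 1) without 1 replicate number. For S against G1, macrophage genes had 0.0338 when arrays were averaged by Eif2s3y detection, against 1.07 with all arrays. There the direction in camera changed while the median stayed positive.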

Other observations

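The values here were noticed after the data were seen. Eif2s3y was detected on 10 arrays and Xist on the other 6. Arrays of 1 group that matched in this respect correlated at 0.984 to 0.995 (6 pairs of arrays), and arrays of 1 group that did not at 0.881 to 0.977 (8 pairs of arrays). For 20 of the tested probes, 19 of them from 16 named genes, the lowest array with Eif2s3y detected lay more than 2 log2 units above the highest array without it, and 2 of these genes lie on the X or Y chromosome. For 0 tested probes was the gap the other way. A probe detected only on the Xist arrays could not be tested, since every group held an array with Eif2s3y detected. Xist itself was left out in this way. The direction of the gaps and the count on X or Y therefore depend on this filter. Eif2s3y (6.35), Zfp330 (4.71), Pdrg1 (4.34), Mcm6 (4.23) and Thumpd1 (4.11) had the widest gaps.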
